A study of Homo sapiens and Mus musculus with 24 samples.

How the data were processed

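RNA was sequenced from AMO1 cells and from whole 5TGM1 tumours, 24 libraries in 8 groups of 3. RNA was extracted with a Qiagen RNeasy kit, per the labels' protocols. The values deposited by the authors are raw counts of reads per gene, in 1 table for AMO1, 1 for the WT tumours and 1 for the CALR KO tumours. All values were whole numbers of at least 0 that summed to a different total in each library. The submitters' processing notes name STAR, an aligner, DESeq2 and the genome builds hg19 and mm9. Their versions, the gene annotation, the counting program and whether it used strand are not given in the sources used here. Counts of overlapping and antisense genes and of near-identical copies may therefore be shared or split. The AMO1 table lists 20114 genes, of which 17803 symbols are in the reference's table of gene names, and genes are named as the tables name them. The mouse tables list 24047 and 24982 rows, and the tests use the 22961 symbols that both hold. Of the rows that were left out, 92 belong to spike-in controls that the WT tumour table lists at 0. Coordinates are left out, because the builds in the processing notes differ from those of the reference at hand. Another 12 columns of per-sample values, some of them with WT in their names in the CALR KO table, could not be tied to a sample by its labels and were not used here.

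Each library was placed in its group by its title, and each column by a name read as the title of a single sample. In the column names "plus" was read as with BTZ, "TING_KO" as STING KO and "ICM" as IMC, and a trailing R was left aside. The labels name a separate mouse for each tumour, and only number the AMO1 samples. Lower bounds of fold changes against groups at 0 use a floor of 3 counts over the group and cover counting error only, and the reads carry no stated molecular identifiers. No pair of replicates matched within sampling noise in a chi-square test of counts over genes with at least 20 counts, so each library was counted once.

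The 9 comparisons were BTZ within each genotype, the difference of both BTZ effects and the genotypes without BTZ, in each system, and in AMO1 also the genotypes with BTZ. Genotypes of the tumours with BTZ were not compared directly. All 12 libraries of a system entered 1 model with 4 group means in edgeR 4.0.16 under R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled by TMM, and the quasi-likelihood test was two-sided with Benjamini-Hochberg adjustment at an FDR of 0.05. Adjusted p-values of single genes are from this test. Log2 fold changes are the coefficients of this model, and CPM are scaled by TMM. Fixed before the data were examined were 24 human and 39 mouse gene lists, which include markers of the other cells a tumour could hold. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Intervals are at 95%. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

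Named genes were chosen by a rule fixed at the same time. It takes the targeted gene, and the 8 largest rises and 8 largest falls among genes past the FDR with a mean of at least 5 CPM and no overlap between the compared libraries. For differences of BTZ effects it takes 5 and 5 without the condition on overlap. From each list it takes up to 4 members with the smallest adjusted p, or the member with the smallest p where none passed. The text gives part of these genes, some are not reported here, and any other is said to be chosen after its values were seen. With 3 libraries against 3, groups fail to overlap by chance for 10% of genes.

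The model was tested on simulated counts drawn from the real means and library sizes with 200 genes changed. Of changes of 1.5, 2 and 4 fold, 81.8%, 94% and 100% were recovered for BTZ in AMO1 WT, with 10 of 11738 unchanged genes called among 11957 tested. For the AMO1 difference of BTZ effects it was 74.2%, 89.6% and 95.5%, with 6 of 11739 among 11958. For BTZ in WT tumours it was 0%, 4.48% and 56.1%, with 3 of 13372 among 13588, and for the tumour difference 0%, 0% and 22.7%, with 0 of 13395 among 13612.

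Alternatives to these choices were DESeq2 1.42.0, limma-voom, RLE size factors, library totals alone, no filter, a strict filter of at least 5 CPM in at least 3 libraries, the replicate number as a block, a fit of the compared libraries alone, leaving out each library in turn, camera with an estimated correlation and the fry rotation test. Leaving out both WT tumours that stood apart on principal components, leaving out the counts of Rn45s, and fitting CALR KO against WT tumours on their 6 libraries alone were added after the data were seen.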

Results

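RNA sequencing counts were analysed from 24 libraries in 8 groups of 3. AMO1 is a human multiple myeloma cell line. Its wild-type (WT) cells and cells labelled STING knockout (KO) were cultured with or without bortezomib (BTZ) at 5 nM overnight. BTZ is a proteasome inhibitor used against multiple myeloma. 5TGM1 is a mouse myeloma line, and tumours were grown from its WT or calreticulin (CALR) KO cells under the skin of C57BL/KaLwRijHsd mice, with or without BTZ given into the peritoneum at 0.5 mg/kg. STING relays the detection of DNA in the cytosol by the sensor cGAS to type I interferon genes. Calreticulin is a chaperone of the endoplasmic reticulum (ER) that acts as a signal for phagocytosis when it is exposed on dying cells. The series title places the study around an immune response to BTZ that runs through cGAS and STING. Total counts per library ranged from 12873064 to 46381278 in AMO1 and from 11673016 to 30103177 in the tumours. The labels number the AMO1 samples without saying that they came from separate cultures, so their p-values measure only the spread between these samples, which may be technical. Levels are given in CPM, counts scaled by the effective library size, as mean ± SD with n = 3, and changes as log2 fold changes ± standard error (SE).

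TMEM173, the gene that encodes STING, stood at 18.1 ± 1.98 CPM in AMO1 WT and 19.6 ± 1.67 CPM in the libraries labelled STING KO without BTZ. This log2 difference of 0.10 ± 0.088 was not called by edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.317). With BTZ it was at 26.5 ± 1.79 CPM in WT and 21.8 ± 0.874 CPM in the libraries labelled STING KO, a called difference of -0.27 ± 0.088 (edgeR adjusted p = 0.0117). The BTZ effects differed by -0.38 ± 0.12 (edgeR adjusted p = 0.0364). The difference with BTZ (-0.23) was not called without STING KO BTZ replicate 1. That of the effects (-0.25 to -0.39) was not called without WT replicate 1 or 3 or WT BTZ replicate 2 or 3 or STING KO replicate 1 or 3 or STING KO BTZ replicate 1 or 2. With library totals alone neither was called (-0.12 and -0.34), nor with RLE size factors that of the effects (-0.35). The RNA level gives no check of that label, because a small edit in an exon can leave RNA in place, so "STING KO" in a library's name gives its label only. In the tumours, Calr, which encodes calreticulin, was at 2020 ± 473 CPM in WT and 362 ± 17 CPM in CALR KO without BTZ (-2.48 ± 0.26, edgeR adjusted p = 8.74e-05). With BTZ it was at 2150 ± 252 CPM in WT and 594 ± 135 CPM in CALR KO tumours. The effect of BTZ on Calr was not called in WT (0.095 ± 0.24, adjusted p = 0.806) or CALR KO tumours (0.72 ± 0.25, adjusted p = 0.133).

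**Figure D1:**
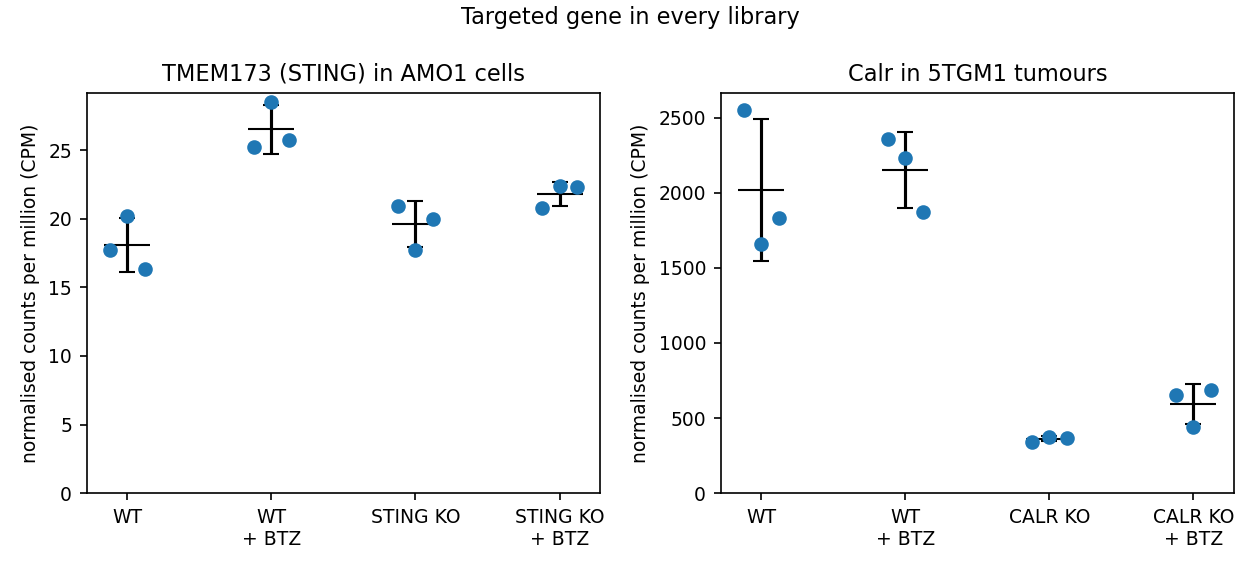
CPM of the targeted genes in each library (points) with the group mean and SD (n = 3 per group), TMEM173 in AMO1 and Calr in 5TGM1 tumours. TMEM173 averages 18.1 to 26.5 CPM over the 4 AMO1 groups, while Calr averages 362 and 594 CPM in the CALR KO groups against 2020 and 2150 CPM in the WT groups.

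The AMO1 WT libraries addressed what BTZ does to transcription in cells with STING. With BTZ, 16 of 19 heat shock chaperone and 14 of 16 NRF2 target genes rose, and 18 of 19 DNA replication, 21 of 21 mitosis and 12 of 17 cholesterol synthesis genes fell. HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, rose from 11.5 ± 0.585 to 465 ± 29 CPM (5.33 ± 0.092, edgeR adjusted p = 8.2e-18). CLU, which encodes the extracellular chaperone clusterin, rose from 8.58 ± 0.394 to 169 ± 6.85 CPM (4.30 ± 0.07). HSPA1B, a stress-inducible HSP70 chaperone gene, rose by 4.73 ± 0.14, a value that is uncertain because HSPA1A is a near-identical copy. Further large rises were those of MLLT11 (4.11 ± 0.081) and OSGIN1 (3.83 ± 0.18), of ZFAND2A, an arsenite- and heat-inducible regulator of the proteasome (3.55 ± 0.067), and of the AP-1 transcription factor JUN (3.38 ± 0.095). CDCA7, a MYC and E2F target, fell from 36.5 ± 1.54 to 4.48 ± 0.634 CPM (-3.0 ± 0.10). CAV1, which encodes the membrane scaffold caveolin 1 (-2.68 ± 0.11), cyclin D1 (CCND1, -2.58 ± 0.14) and the phosphatase gene PTPN6 (-2.50 ± 0.082) fell as well.

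For each gene list fixed before the data were examined, counts adjusted over the list alone are given where they differ from those over all genes, and were the same elsewhere. The p with an estimated correlation between members is given where it ended camera's call, which held elsewhere. Members in brackets beside a count of 5 or fewer were chosen after their values were seen, unless the naming rule gives them. Of the heat shock chaperones, 16 of 19 members rose and 3 were not called (camera adjusted p = 1.49e-07). HSPA8 was at 2.0 ± 0.061. Of the proteasome subunits, 30 of 32 members rose, 1 fell (PSMD7 at -0.15 ± 0.055) and 1 was not called (camera adjusted p = 1.71e-12, adjusted p = 0.0702 with an estimated correlation). PSMC4 (1.75 ± 0.055) and PSMD6 (1.44 ± 0.055) rose most among the subunits named here, and PSMD7 lost its call without WT replicate 2 (-0.14). Among ER chaperones and genes of the unfolded protein response, 19 of 19 members rose (camera adjusted p = 5.89e-09). They included the ER HSP70 gene HSPA5 (2.39 ± 0.056), HSP90B1 (1.81 ± 0.072) and CALR (1.23 ± 0.063). In the integrated stress response, driven by ATF4 and CHOP, 18 of 19 members rose and 1 was not called (camera adjusted p = 6.92e-09). DDIT3, which encodes CHOP, rose by 3.13 ± 0.078, ATF3 by 3.0 ± 0.11 and the cystine transporter gene SLC7A11 by 3.33 ± 0.11.

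Of the targets of NRF2, the regulator of antioxidant genes, 14 of 16 members rose and 2 were not called (15 up adjusted over the list alone, camera adjusted p = 5.53e-07). For autophagy and ubiquitin genes, 11 of 13 members rose, 1 fell (BAG1 at -0.18 ± 0.054) and 1 was not called (camera adjusted p = 1.05e-06). The autophagy receptor gene SQSTM1 rose by 2.46 ± 0.08. Of the p53 targets, 9 of 16 members rose, 2 fell (TP53I3 at -0.66 ± 0.23 and FDXR at -0.27 ± 0.099) and 5 were not called (camera adjusted p = 0.0171, adjusted p = 0.106 with an estimated correlation). Without WT BTZ replicate 1 TP53I3 was at -1.05. TP53I3 (-0.40 to -0.62) lost its call without WT replicate 1 or WT BTZ replicate 3. FDXR (-0.22 to -0.26) lost its call without WT BTZ replicate 1 or 3.

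Of the genes of DNA replication, 1 of 19 members rose (RRM1 at 0.40 ± 0.057) and 18 fell (camera adjusted p = 1.72e-08). The helicase subunit gene MCM4 (-1.40 ± 0.055) and the thymidylate synthase gene TYMS (-1.29 ± 0.055) were among those that fell. Of the mitosis genes, 21 of 21 members fell (camera adjusted p = 5.89e-09), such as topoisomerase TOP2A (-1.52 ± 0.064) and the anaphase activator CDC20 (-1.90 ± 0.092). In cholesterol synthesis, 1 of 17 members rose (STARD4 at 0.44 ± 0.098), 12 fell and 4 were not called (1 up and 13 down adjusted over the list alone, camera adjusted p = 0.00014). The squalene epoxidase gene SQLE fell by 1.05 ± 0.05 on the log2 scale. For the presentation of peptides on MHC class I, 2 of 14 members rose (HLA-C at 0.35 ± 0.081 and B2M at 0.16 ± 0.053), 9 fell and 3 were not called (camera adjusted p = 0.0258, adjusted p = 0.462 with an estimated correlation). The immunoproteasome subunit gene PSMB9 was at -1.35 ± 0.085 and the peptide transporter gene TAP1 at -0.94 ± 0.075. B2M (0.11 to 0.15) lost its call without WT replicate 1 or 3 or WT BTZ replicate 1 or 3. Scaled by library totals alone B2M was at -0.041.

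Interferon-stimulated genes went both ways, and 14 of 28 members rose, 7 fell and 7 were not called (camera adjusted p = 0.0145, adjusted p = 0.0565 with an estimated correlation). IFIT3 rose from 2.91 ± 0.18 to 17 ± 1.08 CPM (2.55 ± 0.098, edgeR adjusted p = 2.81e-13), and OASL (2.47 ± 0.13), IFI44 (3.33 ± 0.20) and STAT2 (1.30 ± 0.054) rose too. Of the components of the cGAS-STING pathway, 5 of 14 members rose (IFI16 at 1.15 ± 0.07, TBK1 at 1.21 ± 0.099, TMEM173 at 0.54 ± 0.09, TREX1 at 0.68 ± 0.15 and IRF3 at 0.21 ± 0.081), 7 fell and 2 were not called (camera adjusted p = 0.476). MB21D1, which encodes cGAS, fell from 23.8 ± 0.493 to 15.4 ± 0.661 CPM (-0.62 ± 0.071). Of the NF-kB targets and inflammatory cytokines, 8 of 13 members rose, 3 fell (TNFAIP3 at -0.41 ± 0.048, CD83 at -1.14 ± 0.19 and NFKB1 at -0.22 ± 0.058) and 2 were not called (camera adjusted p = 0.131). IRF3 (0.14 to 0.22) lost its call without WT replicate 2 or 3 or WT BTZ replicate 2 or 3.

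By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8047 of 12137 tested genes passed an FDR of 0.05, 3973 higher and 4074 lower. The libraries of both groups did not overlap for 69.5% of genes, against 10% by chance, and in mean log2 CPM they lay apart for each list that camera called. Scaled by library totals alone, 31.2% of the calls were higher in place of 49.4%, and the median log2 fold change of all genes moved from -0.0056 to -0.20, so directions are relative to the scaling.

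The same treatment was compared in the AMO1 libraries labelled STING KO. Here 18 of 19 heat shock chaperone, 32 of 32 proteasome subunit and 19 of 19 ER chaperone and unfolded protein response genes rose. HSPA5 rose from 1300 ± 44 to 12400 ± 246 CPM (3.26 ± 0.058) and HMOX1 from 16.3 ± 1.49 to 500 ± 48.5 CPM (4.95 ± 0.088, edgeR adjusted p = 1.4e-17). HSPA1B, with the same uncertainty as above (5.34 ± 0.13), CLU (3.15 ± 0.061) and DDIT3 (3.08 ± 0.075) were also among the largest rises. Genes that fell included the chemokine receptor gene CXCR3 (-3.05 ± 0.20), the steroid sulfatase gene STS (-2.92 ± 0.069) and GPRC5D, an orphan receptor gene of plasma cells (-2.56 ± 0.088).

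Of the heat shock chaperones, 18 of 19 members rose and 1 was not called (camera adjusted p = 6.22e-11). HSPA8 was at 2.54 ± 0.063. Of the proteasome subunits, 32 of 32 members rose (camera adjusted p = 3.05e-17). PSMC4 was at 1.82 ± 0.056. Among ER chaperones and unfolded protein response genes 19 of 19 members rose (camera adjusted p = 4.21e-15). CALR was at 1.87 ± 0.064. In the integrated stress response, 15 of 19 members rose, 1 fell (SLC7A5 at -0.22 ± 0.088) and 3 were not called (camera adjusted p = 3.27e-07). ATF3 was at 2.68 ± 0.099. SLC7A5 (-0.12 to -0.23) lost its call without STING KO replicate 1 or 3 or STING KO BTZ replicate 1 or 3.

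DNA replication genes were split, and 4 of 19 members rose (RRM2 at 0.82 ± 0.052, RRM1 at 0.62 ± 0.056, CDC6 at 0.30 ± 0.058 and CCNE2 at 0.34 ± 0.077), 11 fell and 4 were not called (camera adjusted p = 0.188). TYMS (-0.54 ± 0.053) and the transcription factor gene E2F1 (-0.79 ± 0.081) were among those that fell. Of the mitosis genes, 17 of 21 members fell and 4 were not called (camera adjusted p = 8.53e-06, adjusted p = 0.122 with an estimated correlation), for example TOP2A (-0.85 ± 0.061) and the survivin gene BIRC5 (-0.95 ± 0.068). In cholesterol synthesis, 2 of 17 members rose (STARD4 at 0.53 ± 0.096 and MVD at 0.32 ± 0.11), 13 fell and 2 were not called (camera adjusted p = 3.57e-05). MVD (0.25 to 0.30) lost its call without STING KO replicate 2 or STING KO BTZ replicate 1 or 2. Of the interferon-stimulated genes, 14 of 28 members rose, 9 fell and 5 were not called (camera adjusted p = 0.108). IFIT3 rose from 2.52 ± 0.138 to 27.8 ± 1.29 CPM (3.45 ± 0.092), and OASL (2.54 ± 0.11) and IFI44 (3.09 ± 0.20) rose. TMEM173 (0.16 ± 0.087, adjusted p = 0.116) and MB21D1 (-0.0045 ± 0.065, adjusted p = 0.959) were not called.

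In this comparison 7340 of 12137 tested genes passed an FDR of 0.05, 3354 higher and 3986 lower by edgeR. The groups did not overlap for 62.9% of genes, against 10% by chance, nor in mean log2 CPM for any list that camera called. Library totals alone put 27.8% of the calls higher in place of 45.7% and moved the median log2 fold change of all genes from -0.033 to -0.19.

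The difference between both BTZ effects, libraries labelled STING KO minus WT, was tested in a single model over the 12 AMO1 libraries. BTZ effects on S phase genes and ER chaperones were higher in the libraries labelled STING KO. CDC6, which loads the replicative helicase on DNA, differed by 1.55 ± 0.084 on the log2 scale (edgeR adjusted p = 5.6e-09), RRM2 by 0.99 ± 0.074 and the helicase gene MCM4 by 0.97 ± 0.076. A member that rose had a higher effect there. Of the DNA replication genes, 18 of 19 members rose and 1 was not called (19 up adjusted over the list alone, camera adjusted p = 1.19e-20). In the ER list, 15 of 19 members rose and 4 were not called (camera adjusted p = 7.73e-11), among them HSPA5 (0.87 ± 0.075), the disulfide isomerase gene PDIA4 (0.95 ± 0.078) and CALR (0.65 ± 0.088). Of the mitosis genes, 16 of 21 members rose and 5 were not called (16 up and 1 down adjusted over the list alone, camera adjusted p = 3.91e-10, adjusted p = 0.0718 with an estimated correlation), for example the kinase gene AURKB (1.29 ± 0.097) and the ubiquitin-conjugating enzyme gene UBE2C (1.24 ± 0.097). For heat shock chaperones, 8 of 19 members rose, 2 fell (DNAJB4 at -0.90 ± 0.24 and HSPE1 at -0.35 ± 0.11) and 9 were not called (11 up and 2 down adjusted over the list alone, camera adjusted p = 0.00153, adjusted p = 0.184 with an estimated correlation). The number of chaperones that rose was 5 without WT replicate 1. HSPE1 (-0.25 to -0.34) lost its call without WT replicate 2 or 3 or WT BTZ replicate 3 or STING KO replicate 1 or 2 or STING KO BTZ replicate 1 or 2.

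Other effects were lower in the libraries labelled STING KO. In the integrated stress response, 8 of 19 members fell and 11 were not called (camera adjusted p = 0.000116, adjusted p = 0.0819 with an estimated correlation). SLC7A11, whose BTZ effect was 3.33 in WT, differed by -1.99 ± 0.14, and CTH, an enzyme gene of cysteine synthesis, by -1.60 ± 0.12. Of the p53 targets, 9 of 16 members fell and 7 were not called (camera adjusted p = 0.00125, adjusted p = 0.0772 with an estimated correlation), with the cell cycle inhibitor genes CDKN1A (-0.65 ± 0.12) and BTG2 (-0.56 ± 0.08). Of the replication-dependent histone genes, whose near-identical copies make each value uncertain, 6 of 11 members fell and 5 were not called (7 down adjusted over the list alone, camera adjusted p = 0.000339, adjusted p = 0.115 with an estimated correlation). HIST1H2AC was at -1.75 ± 0.12 and HIST1H2BD at -1.78 ± 0.23. Among the largest single differences were NAT8L (1.55 ± 0.23), NANOS1 (1.41 ± 0.17), SH2D5 (1.39 ± 0.19) and SAPCD2 (1.38 ± 0.20) on the higher side. ZNF608, a transcription cofactor gene (-1.80 ± 0.14), and the potassium channel gene KCNN3 (-1.75 ± 0.098) lay on the lower side. MB21D1 differed by 0.61 ± 0.097 (edgeR adjusted p = 0.000186). For interferon-stimulated genes, 3 of 28 members rose (IFIT3 at 0.90 ± 0.14, RSAD2 at 1.34 ± 0.29 and IFIT2 at 0.97 ± 0.29), 6 fell and 19 were not called (camera adjusted p = 0.139), and OAS2 was lower (-0.62 ± 0.11). Their mean score differed by -0.152 on the log2 CPM scale (95% interval -0.244 to -0.0593). IFIT2 (0.83 to 0.94) lost its call without WT replicate 2 or STING KO replicate 2 or STING KO BTZ replicate 1.

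Over all genes, 2829 of 12137 differed between the BTZ effects by edgeR at an FDR of 0.05, 1334 higher and 1495 lower in the libraries labelled STING KO. With library totals alone 57.3% of the calls were higher in place of 47.2%. Without WT replicate 3 or STING KO replicate 1, 2 or 3 the lower calls numbered 780, 940, 892 and 845, and 63 to 64.6% of the calls were higher. Across the 12137 genes, which are not independent replicates, the effects correlated with a Pearson r of 0.786 and a Spearman rho of 0.796, and no control library was shared. BTZ raised 2723 genes in both backgrounds, against 1098 for independent lists, and lowered 3028, against 1338. Called higher in WT and lower in the libraries labelled STING KO were 97 genes, and 72 the reverse.

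**Figure D2:**
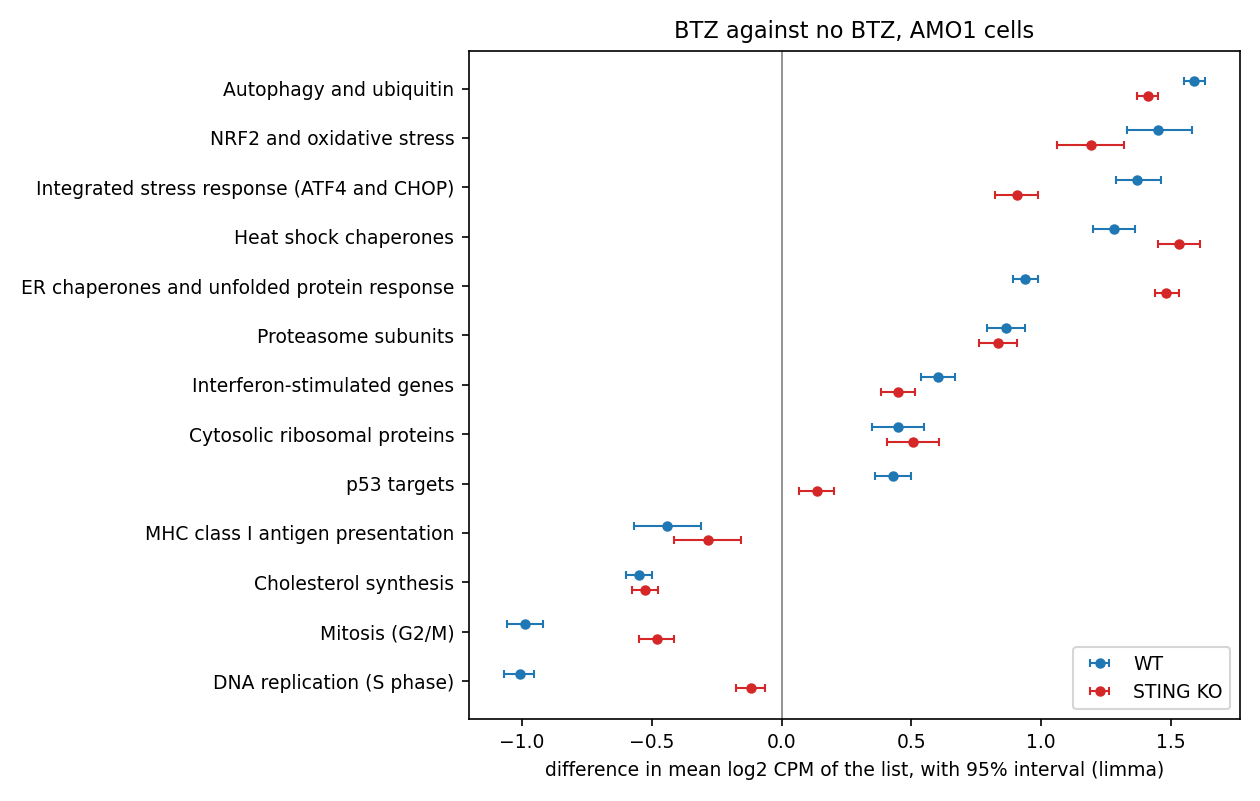
Difference in mean log2 CPM of gene lists in AMO1 with BTZ against without, with 95% intervals (limma), in WT and in the libraries labelled STING KO. Lists that camera called in either are shown. The DNA replication list lies lower in WT than in the libraries labelled STING KO by 0.893. The ER chaperone list lies higher in the latter by 0.544.

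Without BTZ, the AMO1 libraries labelled STING KO were compared with WT to show how the populations differed before treatment. In the libraries labelled STING KO 21 of 21 mitosis genes were higher and 13 of 17 cholesterol synthesis genes lower. DHRS2, a mitochondrial reductase gene, was at 1.44 ± 0.191 CPM in WT and 19.9 ± 2.25 CPM in the libraries labelled STING KO (3.82 ± 0.15, edgeR adjusted p = 1.11e-12), and HIST1H2BJ, uncertain as a histone gene, was also higher (3.50 ± 0.11). The transcription factor gene SOX5 was at 18.5 ± 1.53 CPM in WT and 0.309 ± 0.022 CPM in the libraries labelled STING KO (-5.87 ± 0.17). The myosin gene MYO1F (-4.95 ± 0.18) and the proteoglycan gene SPOCK2 (-4.07 ± 0.15) were lower too. For the lists, a member that rose was higher in the libraries labelled STING KO.

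Of the mitosis genes, 21 of 21 members rose (camera adjusted p = 2.73e-13), among them KIF20A (1.76 ± 0.068) and PLK1 (1.83 ± 0.085). In the integrated stress response, 13 of 19 members rose, 3 fell (ATF5 at -0.91 ± 0.098, PPP1R15A at -0.29 ± 0.082 and DDIT4 at -0.30 ± 0.11) and 3 were not called (camera adjusted p = 8.47e-05, adjusted p = 0.0785 with an estimated correlation). Of the interferon-stimulated genes, 2 of 28 members rose (HERC5 at 1.06 ± 0.11 and OAS2 at 0.61 ± 0.078), 13 fell and 13 were not called (camera adjusted p = 0.0138, adjusted p = 0.0785 with an estimated correlation). The antiviral GTPase gene MX1 was at 5.17 ± 0.041 CPM in WT and 0.556 ± 0.0923 CPM in the libraries labelled STING KO (-3.24 ± 0.17), and RSAD2 (-3.44 ± 0.22) was lower. Of the MHC class II genes, 10 of 10 members fell (camera adjusted p = 1.05e-06, adjusted p = 0.148 with an estimated correlation), for example HLA-DQA1 (-1.27 ± 0.053) and HLA-DRB1 (-1.20 ± 0.064), which belong to a family of alike and variable genes and are uncertain. In cholesterol synthesis, 1 of 17 members rose, 13 fell and 3 were not called (camera adjusted p = 1.51e-05). INSIG1, which retains the sterol sensor in the ER, was at -1.49 ± 0.056, and the number that rose was 0 by edgeR (0 to 1 at an unadjusted p under 0.05) without any one of the 6 libraries. DDIT4 (-0.24 to -0.31) lost its call without WT replicate 2 or 3 or STING KO replicate 2.

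Genes of MYC and ribosome biogenesis were lower, and 16 of 16 members fell (camera adjusted p = 1.5e-06, adjusted p = 0.0712 with an estimated correlation), including MYC itself (-0.87 ± 0.073) and RRP12 (-0.77 ± 0.055). In the plasma cell identity list, 3 of 13 members rose (CD38 at 0.77 ± 0.063, FAM46C at 0.23 ± 0.053 and FKBP11 at 0.17 ± 0.061), 9 fell and 1 was not called (camera adjusted p = 0.0111, adjusted p = 0.139 with an estimated correlation). The transcription factor gene IRF4 was at -0.77 ± 0.058 and the B cell coactivator gene POU2AF1 at -1.38 ± 0.079. FKBP11 (0.11 to 0.16) lost its call without WT replicate 2 or 3 or STING KO replicate 1 or 3. Between these groups 7231 of 12137 tested genes passed an FDR of 0.05, 3706 higher and 3525 lower in the libraries labelled STING KO. The groups did not overlap for 67.2% of genes, against 10% by chance, nor in mean log2 CPM for the lists camera called. With library totals alone 66.5% of the calls were higher in place of 51.3%, and the median of all genes moved from 0.0037 to 0.11.

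With BTZ, the same populations were compared once more. RRM2 was at 442 ± 14.9 CPM in WT with BTZ and 1300 ± 49.3 CPM in the libraries labelled STING KO with BTZ (1.56 ± 0.053, edgeR adjusted p = 1.24e-13). Of the DNA replication genes, 19 of 19 members rose (camera adjusted p = 2.19e-10). The helicase cofactor gene GINS2 was at 1.74 ± 0.065. Of the mitosis genes, 21 of 21 members rose (camera adjusted p = 7.81e-14). AURKB was at 2.64 ± 0.073 and TOP2A at 2.01 ± 0.064. Among the largest single differences were higher DHRS2 (4.68 ± 0.23) and the semaphorin receptor gene PLXND1 (3.87 ± 0.14), and lower SOX5 (-6.94 ± 0.18) and the galectin gene LGALS8 (-6.99 ± 0.22).

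Of the interferon-stimulated genes, 3 of 28 members rose (HERC5 at 1.27 ± 0.11, IFIT3 at 0.69 ± 0.078 and OASL at 0.28 ± 0.099), 17 fell and 8 were not called (camera adjusted p = 0.00377, adjusted p = 0.0563 with an estimated correlation). MX1 was at 11.9 ± 1.65 CPM in WT with BTZ and 0.618 ± 0.108 CPM in the libraries labelled STING KO with BTZ (-4.29 ± 0.16). Of the MHC class II genes, 10 of 10 members fell (camera adjusted p = 1.92e-05, adjusted p = 0.226 with an estimated correlation). HLA-DQA1 was at -1.35 ± 0.053. MB21D1 was higher in the libraries labelled STING KO (0.78 ± 0.071, edgeR adjusted p = 2.85e-08). OASL (0.26) lost its call without WT BTZ replicate 1.

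In all, 8157 of 12137 tested genes passed an FDR of 0.05, 3833 higher and 4324 lower. The groups did not overlap for 66.6% of genes, against 10% by chance, nor in mean log2 CPM for the called lists. Library totals alone gave 62.9% of calls higher in place of 47%, and a median of all genes of 0.11 in place of -0.035.

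In the 5TGM1 WT tumours, BTZ was compared with no BTZ in whole tumours, which hold myeloma cells and cells of the host. With BTZ 30 of 34 interferon-stimulated genes rose and 18 of 21 mitosis genes fell. Rsad2, an antiviral enzyme gene, rose from 20.5 ± 1.45 to 209 ± 39 CPM (3.35 ± 0.21, edgeR adjusted p = 3.22e-06). Prf1, which encodes the pore-forming protein of killer cells, rose from 17.4 ± 3.85 to 102 ± 9.19 CPM (2.55 ± 0.23). Of the interferon-stimulated genes, 30 of 34 members rose and 4 were not called (32 up adjusted over the list alone, camera adjusted p = 8.8e-20). They included Oasl1 (3.58 ± 0.33), Mx1 (2.84 ± 0.28) and the chemokine gene Cxcl10 (2.87 ± 0.34). Of the interferon-gamma response genes, 16 of 19 members rose and 3 were not called (camera adjusted p = 1.04e-09, adjusted p = 0.103 with an estimated correlation). The GTPase gene Gbp5 was at 2.24 ± 0.30. Of the NF-kB targets and inflammatory cytokines, 12 of 19 members rose and 7 were not called (camera adjusted p = 4.2e-06). The chemokine gene Ccl3 was at 3.12 ± 0.43 and Ccl2 at 2.11 ± 0.34. Of the NRF2 targets, 11 of 16 members rose and 5 were not called (13 up adjusted over the list alone, camera adjusted p = 1.6e-06, adjusted p = 0.0931 with an estimated correlation). The sulfiredoxin gene Srxn1 was at 4.13 ± 0.32 and Gclm, a gene of glutathione synthesis, at 1.94 ± 0.22.

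For mitosis genes, 18 of 21 members fell and 3 were not called (19 down adjusted over the list alone, camera adjusted p = 5.71e-11), such as Kif11 (-1.75 ± 0.22) and Ccnb1 (-1.91 ± 0.24). For DNA replication genes, 10 of 20 members fell and 10 were not called (12 down adjusted over the list alone, camera adjusted p = 1.74e-05, adjusted p = 0.103 with an estimated correlation). Cdc6 was at -1.32 ± 0.19, and the number that fell was 6 without WT BTZ replicate 3 and 16 without WT replicate 1. In cholesterol synthesis, 3 of 17 members rose (among them Stard4 at 1.71 ± 0.58), 8 fell and 6 were not called (3 up and 10 down adjusted over the list alone, camera adjusted p = 0.0027, adjusted p = 0.218 with an estimated correlation), and the isomerase gene Idi1 was at -2.52 ± 0.36. Stard4 lost its call without WT replicate 1, 2 or 3 (1.53 to 1.83) or WT BTZ replicate 3 (0.41). In the same refits the number of sterol genes that rose was 0 by edgeR (1 to 3 at an unadjusted p under 0.05). In the integrated stress response, 2 of 20 members rose (Atf3 at 1.98 ± 0.48 and Cebpb at 1.24 ± 0.40), 8 fell and 10 were not called (2 up and 11 down adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.43 with an estimated correlation), and the enzyme genes of amino acid synthesis Cth (-2.62 ± 0.32) and Psat1 (-2.05 ± 0.34) fell. Atf3 stood at 1.07 without WT BTZ replicate 3. Cebpb (0.80 to 1.32) lost its call without WT replicate 1 or 2 or WT BTZ replicate 1 or 3. The number of stress response genes that fell was 4 without WT BTZ replicate 2 and 5 without WT replicate 3 or WT BTZ replicate 1. Reln, which encodes the matrix protein reelin (-3.36 ± 0.55), and Fkbp11, a folding enzyme gene of the ER (-2.54 ± 0.42), fell as well.

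For T cell genes in the WT tumours, 9 of 14 members rose, 1 fell and 4 were not called (12 up and 1 down adjusted over the list alone, camera adjusted p = 7.02e-05, adjusted p = 0.187 with an estimated correlation). The kinase gene Zap70 was at 1.94 ± 0.36. For cytotoxic effector genes, 10 of 14 members rose and 4 were not called (11 up adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.0931 with an estimated correlation). The granzyme gene Gzmb was at 2.39 ± 0.38 and Cd8a at 1.69 ± 0.31. For regulatory T cells and checkpoints, 9 of 10 members rose and 1 was not called (camera adjusted p = 5.73e-08), with the inhibitory receptor genes Ctla4 (3.29 ± 0.39) and Lag3 (2.74 ± 0.40) and the costimulator gene Icos (3.48 ± 0.44). For macrophage genes, 7 of 15 members rose and 8 were not called (camera adjusted p = 0.000235, adjusted p = 0.0931 with an estimated correlation). Csf1r was at 1.37 ± 0.26, and the number that rose was 12 without WT replicate 1. For monocyte and neutrophil genes, 9 of 12 members rose and 3 were not called (camera adjusted p = 6.36e-06, adjusted p = 0.0931 with an estimated correlation). Chil3 was at 5.26 ± 0.52. For dendritic cell genes, 5 of 10 members rose (Itgax at 2.34 ± 0.25, Fscn1 at 2.38 ± 0.32, Ccr7 at 3.93 ± 0.53, Flt3 at 1.81 ± 0.61 and Siglech at 2.0 ± 0.69) and 5 were not called (camera adjusted p = 0.0126, adjusted p = 0.218 with an estimated correlation). Flt3 (1.60 to 1.95) and Siglech (1.61 to 2.26) lost their calls without WT replicate 1, 2 or 3 or WT BTZ replicate 1 or 2. The list was not called without WT replicate 2 (camera adjusted p = 0.0919). For fibroblast and matrix genes, 11 of 14 members rose and 3 were not called (13 up adjusted over the list alone, camera adjusted p = 5.73e-08, adjusted p = 0.103 with an estimated correlation). The collagenase gene Mmp2 was at 3.39 ± 0.39, and for endothelial genes 10 of 13 members rose and 3 were not called (11 up and 1 down adjusted over the list alone, camera adjusted p = 1.6e-06, adjusted p = 0.0931 with an estimated correlation). Pecam1 was at 1.47 ± 0.21. A lower share of tumour cells would raise host lists together. It was not tested for these rises, the mitosis fall or the CALR KO minus WT differences. EdgeR called 0 of 7 natural killer, 0 of 7 B and 0 of 3 erythroid cell genes, with 1, 3 and 1 at an unadjusted p under 0.05, while DESeq2 called 1 higher in each and 1 B cell gene lower, and limma-voom 1 erythroid gene higher.

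Skin and muscle genes had their highest levels in 1 library. For keratinocyte genes, 8 of 8 members rose (camera adjusted p = 0.0295, adjusted p = 0.587 with an estimated correlation), but they summed to 37950 CPM in WT BTZ replicate 3 and to 3.75 to 34.9 CPM in the other 11 tumour libraries. Without that library the keratin gene Krt10, at 14.30 ± 3.37 with it, stood at 1.09 (edgeR adjusted p = 0.409) and the collagen gene Col17a1 at 1.42 in place of 8.10. The camera adjusted p of the list was 0.0806 without WT replicate 1, 0.0783 without WT replicate 2 and 0.247 without WT BTZ replicate 3, and the number of its genes that rose was 0 by edgeR (0 at an unadjusted p under 0.05) without WT BTZ replicate 3, 2 without WT replicate 1 and 3 without WT replicate 2. For skeletal muscle genes, 9 of 10 members rose and 1 was not called (camera adjusted p = 1.74e-05, adjusted p = 0.218 with an estimated correlation). The myosin gene Myh1 was at 4.86 ± 0.78. They summed to 3326 CPM in WT BTZ replicate 3 and to 437 and 586 CPM in the other two treated WT tumours.

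In this comparison 3755 of 13809 tested genes passed an FDR of 0.05, 2178 higher and 1577 lower by edgeR, and the groups did not overlap for 37.6% of genes, against 10% by chance. Fitted on the 6 WT tumours alone the count was 984, and without both WT tumours that stood apart, WT replicate 1 and WT BTZ replicate 3, a choice made after seeing the data, it was 3944. Library totals alone put 76.2% of the calls higher in place of 58% and moved the median of all genes from -0.1 to 0.0719. Without WT BTZ replicate 1 or 2 the lower calls numbered 863 and 975, and 68.2 to 70.2% of the calls were higher. In mean log2 CPM the groups overlapped for the cholesterol synthesis and keratinocyte lists, and not for the other lists here with genes called.

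**Figure D3:**
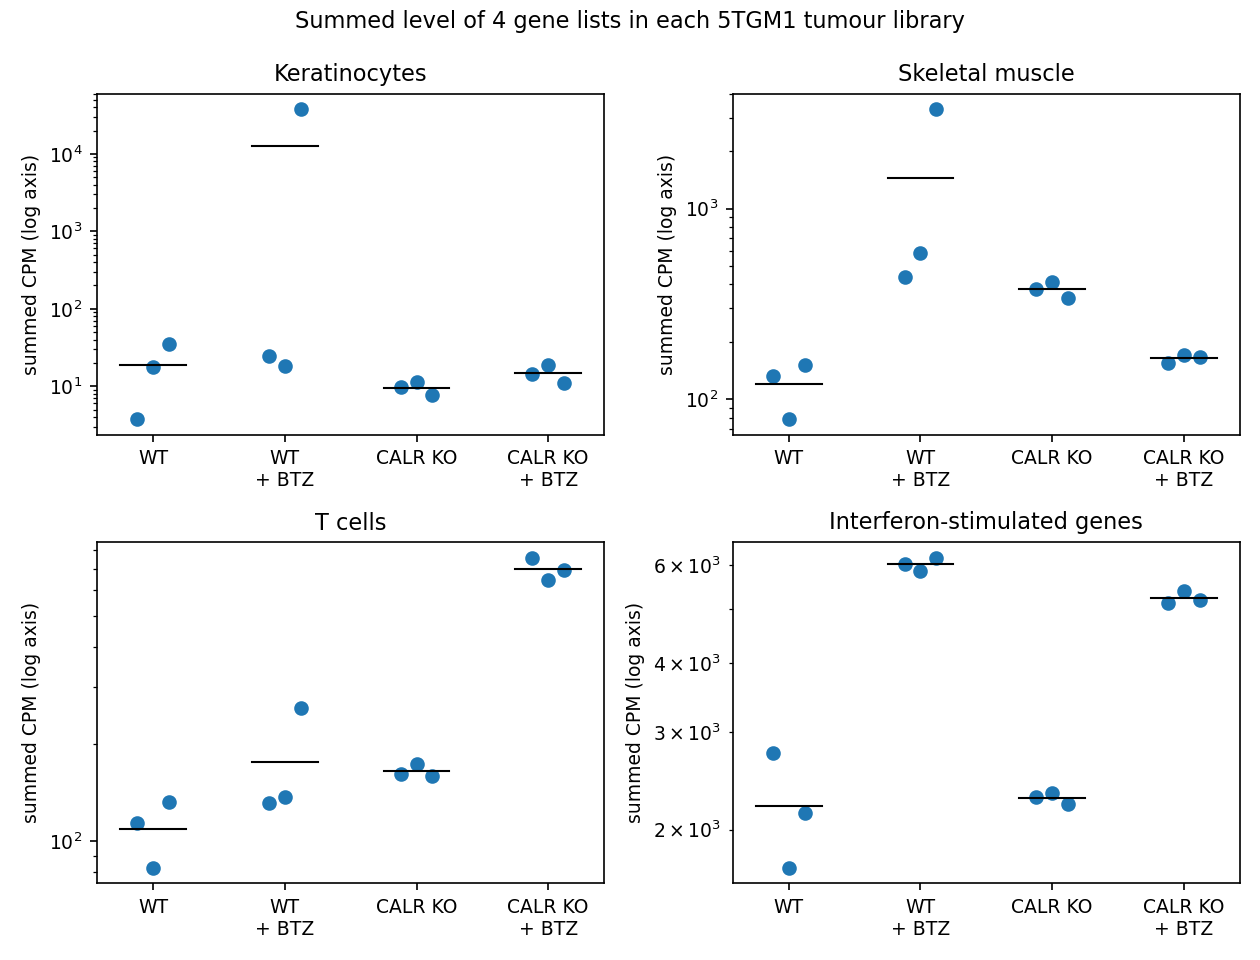
Summed CPM of marker gene lists in each of the 12 tumour libraries on a log axis, by group. Keratinocyte genes reach 37950 CPM in WT BTZ replicate 3, and T cell genes reach 758, 647 and 694 CPM in the CALR KO tumours with BTZ.

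BTZ was compared with no BTZ in the CALR KO tumours, which were grown from cells labelled as lacking calreticulin. Slfn4, an interferon-inducible gene of myeloid cells with close family members, rose from 2.41 ± 0.543 to 115 ± 3.39 CPM (5.59 ± 0.48, edgeR adjusted p = 0.000147). Chil3, a chitinase-like gene of myeloid cells, rose by 3.99 ± 0.51. Of the interferon-stimulated genes, 24 of 34 members rose and 10 were not called (29 up adjusted over the list alone, camera adjusted p = 3.42e-31). Rsad2 rose from 14 ± 1.01 to 149 ± 6.16 CPM (3.41 ± 0.21), and Oas3 (3.78 ± 0.36), Usp18 (3.45 ± 0.40), Ifit3 (3.30 ± 0.30) and Oasl2 (3.15 ± 0.32) rose. For T cell genes, 12 of 14 members rose and 2 were not called (14 up adjusted over the list alone, camera adjusted p = 4.17e-14, adjusted p = 0.0686 with an estimated correlation). They summed to 161, 173 and 160 CPM in the 3 CALR KO tumours and to 758, 647 and 694 CPM with BTZ. Cd3e, which encodes a chain of the T cell receptor complex, rose by 2.91 ± 0.45, and its call was lost at 2.82 without CALR KO replicate 1 and 2.88 without CALR KO replicate 2.

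For cytotoxic effector genes, 7 of 14 members rose and 7 were not called (12 up adjusted over the list alone, camera adjusted p = 7.71e-12, adjusted p = 0.0686 with an estimated correlation). Prf1 was at 1.94 ± 0.23, Cd8a at 2.11 ± 0.31 and the transcription factor gene Tbx21 at 2.51 ± 0.37. For regulatory T cells and checkpoints, 5 of 10 members rose (Havcr2 at 2.25 ± 0.27, Icos at 2.84 ± 0.42, Ctla4 at 2.40 ± 0.37, Pdcd1 at 1.73 ± 0.30 and Lag3 at 1.78 ± 0.38) and 5 were not called (8 up adjusted over the list alone, camera adjusted p = 4.41e-08). Of the interferon-gamma response genes, 10 of 19 members rose and 9 were not called (16 up and 1 down adjusted over the list alone, camera adjusted p = 3.71e-11, adjusted p = 0.147 with an estimated correlation). Cxcl10 was at 2.38 ± 0.33. Of the NF-kB targets and inflammatory cytokines, 5 of 19 members rose (Ccl2 at 1.98 ± 0.34, Ccl3 at 2.03 ± 0.41, Nfkbia at 1.10 ± 0.25, Cxcl2 at 4.98 ± 1.15 and Ccl4 at 2.20 ± 0.53) and 14 were not called (7 up and 1 down adjusted over the list alone, camera adjusted p = 0.00271, adjusted p = 0.147 with an estimated correlation). For endothelial genes, 5 of 13 members rose (Plvap at 2.24 ± 0.31, Esam at 1.85 ± 0.35, Tie1 at 1.64 ± 0.35, Kdr at 1.61 ± 0.37 and Cdh5 at 1.38 ± 0.34) and 8 were not called (8 up adjusted over the list alone, camera adjusted p = 9.2e-07, adjusted p = 0.128 with an estimated correlation). For MHC class II genes, 3 of 7 members fell (H2-Eb1 at -1.79 ± 0.34, H2-Aa at -1.85 ± 0.36 and H2-Ab1 at -1.55 ± 0.35) and 4 were not called (6 down adjusted over the list alone, camera adjusted p = 1.29e-05, adjusted p = 0.221 with an estimated correlation). For macrophage genes, 1 of 15 members rose (Itgam at 1.33 ± 0.24) and 14 were not called (2 up and 3 down adjusted over the list alone, camera adjusted p = 0.91), and for mitosis genes 21 of 21 members were not called (camera adjusted p = 0.958). DESeq2 and limma-voom called 0 of these genes as well, and at an unadjusted p under 0.05 edgeR had 1, DESeq2 2 and limma-voom 1. Ctla4 (2.33 to 2.36) lost its call without CALR KO replicate 1 or 2. Pdcd1 (1.62 to 1.86) and Ccl2 (1.95 to 2.01) lost their calls without CALR KO replicate 1, 2 or 3. Lag3 (1.42 to 1.97), Cxcl2 (4.28 to 6.25), Ccl4 (1.95 to 2.38), Tie1 (1.44 to 1.85), Kdr (1.43 to 1.82), Cdh5 (1.29 to 1.5) and H2-Ab1 (-1.41 to -1.70) lost their calls without any one of the 6 libraries. Ccl3 (1.97 to 2.12), Nfkbia (0.93 to 1.15), Esam (1.72 to 2.01), H2-Aa (-1.66 to -1.96) and Itgam (1.25 to 1.34) lost their calls without CALR KO replicate 1, 2 or 3 or CALR KO BTZ replicate 1 or 3. H2-Eb1 (-1.63 to -1.77) lost its call without CALR KO replicate 1 or 2 or CALR KO BTZ replicate 1 or 3. Tg, the gene of thyroglobulin, fell most among the genes named here (-2.67 ± 0.39).

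Here 350 of 13809 genes passed an FDR of 0.05, 307 higher and 43 lower. The groups did not overlap for 39.3% of genes, against 10% by chance. The count was 57, 54 and 84 without CALR KO replicate 1, 2 or 3. Without CALR KO BTZ replicate 1 or 3 it was 112 and 98. In these refits 1 to 4 were lower. Without 1 library, 0 to 6 T cell genes, 18 to 23 interferon-stimulated genes, 4 to 7 cytotoxic effector genes, 2 to 4 checkpoint genes, 1 to 8 interferon-gamma response genes, 0 to 3 NF-kB targets and 1 to 2 endothelial genes rose, and 0 to 2 MHC class II genes fell. Camera called these 8 lists in each refit, and in mean log2 CPM they set treated apart from control libraries. DESeq2 called 1147 genes, 65.1% higher in place of 87.7%. Fitted on the 6 CALR KO tumours alone, without the spread of the WT tumours, 3136 passed. The WT tumours alone gave 984, not 3755, so these counts do not rank the genotypes.

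The difference between both BTZ effects in the tumours, CALR KO minus WT, was tested in the model over all 12 tumour libraries. Here a member that rose had a higher BTZ effect in CALR KO. For mitosis genes, 6 of 21 members rose and 15 were not called (18 up adjusted over the list alone, camera adjusted p = 5.22e-14). The cyclin gene Ccna2 was at 1.78 ± 0.32 and the checkpoint kinase gene Bub1 at 1.62 ± 0.31. Slc9b1, a sodium-proton exchanger gene, had a higher effect in CALR KO (5.43 ± 0.71, edgeR adjusted p = 0.00639). For skeletal muscle genes, 5 of 10 members fell (Acta1 at -4.63 ± 0.79, Myh1 at -5.81 ± 1.01, Ckm at -6.74 ± 1.34, Atp2a1 at -6.06 ± 1.20 and Tnnt3 at -4.52 ± 0.92) and 5 were not called (9 down adjusted over the list alone, camera adjusted p = 6.37e-09, adjusted p = 0.195 with an estimated correlation), beside the high muscle level of WT BTZ replicate 3. Of the NRF2 targets, 3 of 16 members fell (Srxn1 at -2.91 ± 0.41, Osgin1 at -3.71 ± 0.52 and Fth1 at -2.03 ± 0.41) and 13 were not called (6 down adjusted over the list alone, camera adjusted p = 0.000396, adjusted p = 0.195 with an estimated correlation). For macrophage genes, 2 of 15 members fell (Apoe at -3.75 ± 0.57 and Csf1r at -2.23 ± 0.37) and 13 were not called (5 down adjusted over the list alone, camera adjusted p = 0.000848, adjusted p = 0.195 with an estimated correlation), and for fibroblast and matrix genes 1 of 14 members fell (Mmp2 at -3.36 ± 0.52) and 13 were not called (7 down adjusted over the list alone, camera adjusted p = 1.7e-06, adjusted p = 0.199 with an estimated correlation). For MYC and ribosome biogenesis genes, 1 of 16 members rose (Dkc1 at 1.74 ± 0.35) and 15 were not called (9 up adjusted over the list alone, camera adjusted p = 1.01e-07, adjusted p = 0.195 with an estimated correlation). Of the interferon-stimulated genes, 34 of 34 members were not called (camera adjusted p = 0.887), and their mean score differed by -0.0731 on the log2 CPM scale (95% interval -0.486 to 0.34). DESeq2 and limma-voom called 0 of these genes as well, and at an unadjusted p under 0.05 edgeR had 3, DESeq2 3 and limma-voom 3.

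By edgeR 142 of 13809 genes differed in their BTZ effect, 47 higher and 95 lower in CALR KO. This count was 1217 and 60 without WT replicate 1 or 3, and 278 without WT BTZ replicate 3. It was 14, 12 and 32 without CALR KO replicate 1, 2 or 3. Without CALR KO BTZ replicate 1, 2 or 3 it was 10, 52 and 8. The share of higher calls ran from 9.38% without CALR KO replicate 3 to 57.6% without WT replicate 1. Without both WT tumours that stood apart the count was 2216. With library totals alone 17.4% of the calls were higher in place of 33.1%. Ccna2 (1.67 to 1.89) lost its call without WT replicate 3 or CALR KO replicate 1, 2 or 3 or CALR KO BTZ replicate 1 or 3. Bub1 (1.46 to 1.79) lost its call without WT replicate 3 or WT BTZ replicate 2 or any one CALR KO library. Myh1 (-5.75 to -5.90) lost its call without any one CALR KO library. Srxn1 (-2.76 to -2.83) and Osgin1 (-3.56 to -3.73) lost their calls without CALR KO BTZ replicate 1 or 3. Csf1r (-2.09 to -2.18), Mmp2 (-3.26 to -3.36) and Apoe (-3.66 to -3.72) lost their calls without CALR KO replicate 1 or 2 or CALR KO BTZ replicate 1 or 3. Dkc1 (1.53 to 1.85) lost its call without WT replicate 3 or WT BTZ replicate 1 or 2 or CALR KO replicate 1, 2 or 3 or CALR KO BTZ replicate 1 or 3. Acta1 (-4.46 to -4.82) lost its call without CALR KO replicate 1 or 2 or CALR KO BTZ replicate 1, 2 or 3. Ckm (-6.45 to -7.21), Atp2a1 (-5.91 to -6.50), Tnnt3 (-4.18 to -5.04) and Fth1 (-1.82 to -2.10) lost their calls without WT replicate 2 or 3 or any one CALR KO library. Without WT BTZ replicate 3 Ckm was at -3.89, Atp2a1 at -3.60 and Tnnt3 at -2.92. That refit called 8 muscle genes lower, in place of 5. The refits without 1 library called 0 to 19 mitosis genes and 0 to 10 MYC and ribosome biogenesis genes higher, the most of both without WT replicate 1, and 0 to 9 muscle genes, 0 to 5 NRF2 targets, 0 to 7 macrophage genes and 0 to 7 fibroblast genes lower. Across 13809 genes, the BTZ effects in WT and CALR KO tumours correlated with a Pearson r of 0.418 and a Spearman rho of 0.455, with no shared control library. Called higher in both were 247 genes, against 48.4 for independent lists, and called lower in both 16, against 4.91.

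**Figure D4:**
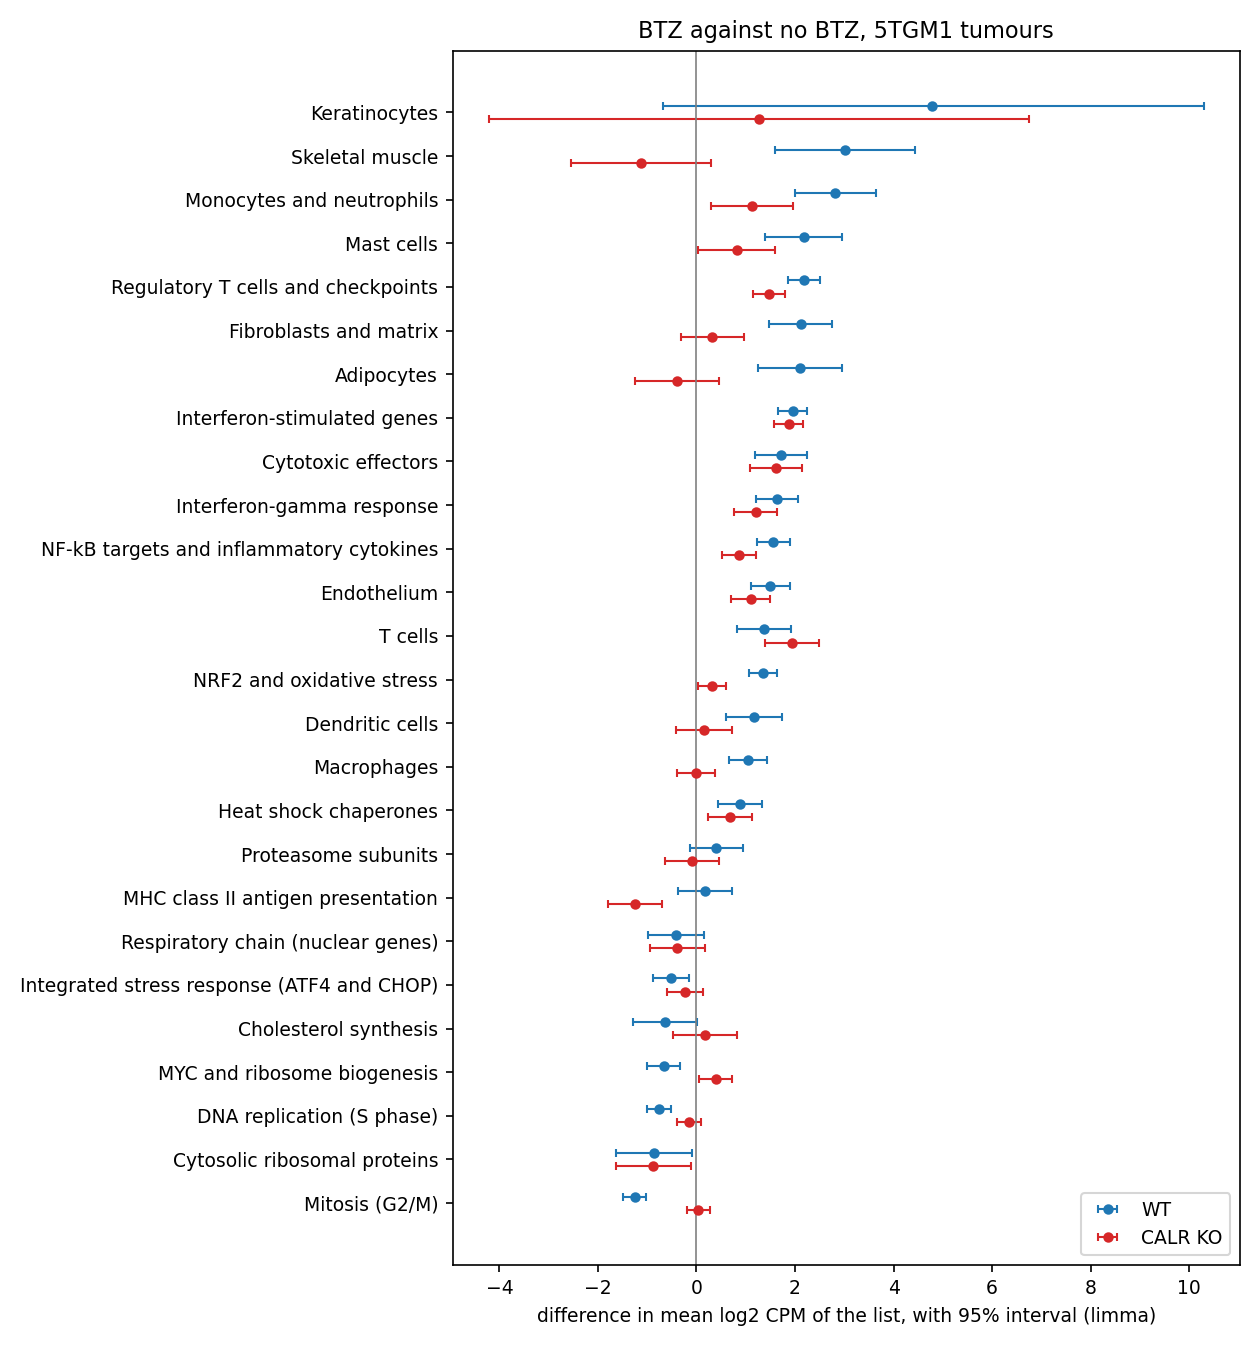
Difference in mean log2 CPM of gene lists in 5TGM1 tumours with BTZ against without, with 95% intervals (limma), in WT and in CALR KO. Lists that camera called in either are shown. The mitosis list lies lower in WT than in CALR KO tumours by 1.29. The interferon-stimulated genes lie at 1.95 in WT and 1.87 in CALR KO.

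Without BTZ, CALR KO tumours were compared with WT tumours. The counts of both genotypes come from separate tables that list different genes, so genotype and table cannot be told apart in this comparison. Columns of the CALR KO table with WT in their names could not be tied to a sample and were not used here. A list member that rose was higher in CALR KO. Cd8a was at 12 ± 6.09 CPM in WT and 38.6 ± 1.42 CPM in CALR KO (1.68 ± 0.31, edgeR adjusted p = 0.0079), and the interferon gene Ifng was higher by 2.0 ± 0.34. For cytotoxic effector genes, 10 of 14 members rose and 4 were not called (12 up adjusted over the list alone, camera adjusted p = 5.49e-11, adjusted p = 0.12 with an estimated correlation). For T cell genes, 7 of 14 members rose, 1 fell and 6 were not called (10 up and 1 down adjusted over the list alone, camera adjusted p = 6.47e-06, adjusted p = 0.279 with an estimated correlation). The receptor chain gene Cd3g was at 2.43 ± 0.45. For regulatory T cells and checkpoints, 4 of 10 members rose (Pdcd1 at 1.55 ± 0.30, Tigit at 1.80 ± 0.39, Ctla4 at 1.58 ± 0.38 and Lag3 at 1.46 ± 0.39) and 6 were not called (6 up adjusted over the list alone, camera adjusted p = 3.54e-05, adjusted p = 0.12 with an estimated correlation). For natural killer cell genes, 2 of 7 members rose (Klre1 at 3.02 ± 0.44 and Klrd1 at 2.08 ± 0.53) and 5 were not called (3 up adjusted over the list alone, camera adjusted p = 0.00189, adjusted p = 0.392 with an estimated correlation). For macrophage genes, 1 of 15 members rose (Mrc1 at 1.56 ± 0.34) and 14 were not called (3 up adjusted over the list alone, camera adjusted p = 3.54e-05, adjusted p = 0.12 with an estimated correlation), and the scavenger receptor gene Marco was higher by 5.76 ± 0.48. For skeletal muscle genes, 1 of 10 members rose (Myh4 at 3.48 ± 0.58) and 9 were not called (6 up adjusted over the list alone, camera adjusted p = 1.27e-05, adjusted p = 0.356 with an estimated correlation). As the difference of mean log2 CPM with its unadjusted 95% interval, B cell genes (0.903, 0.497 to 1.31), fibroblast and matrix genes (1.01, 0.375 to 1.65), adipocyte genes (1.15, 0.291 to 2.01) and mast cell genes (1.14, 0.357 to 1.93) lay higher in CALR KO, and endothelial genes (-0.597, -0.995 to -0.199) and erythroid genes (-1.85, -2.95 to -0.742) lower. The intervals of monocyte and neutrophil genes (0.344, -0.484 to 1.17) and dendritic cell genes (0.298, -0.268 to 0.864) held 0. Interferon-stimulated genes were mostly not called, and 1 of 34 members rose, 3 fell (Oas3 at -2.06 ± 0.34, Oas1a at -1.40 ± 0.32 and Isg15 at -1.41 ± 0.37) and 30 were not called (1 up and 5 down adjusted over the list alone, camera adjusted p = 0.183).

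Other large differences were at 0 in every library of 1 table, treated or not. They may stem from the tables and are lower bounds against 3 counts over the group. Pisd-ps3 was at least 1970-fold and Ndufs5 at least 709-fold higher in the CALR KO table. Rpp14 was at least 1520-fold, Ass1 at least 1210-fold and Trex1 at least 911-fold lower there. By edgeR 654 of 13809 tested genes passed an FDR of 0.05, 366 higher and 288 lower, and the groups did not overlap for 24.9% of genes, against 10% by chance. Of the calls, 8 were at 0 in every library of the WT table and 18 in every library of the CALR KO table. The count was 3591, 312 and 359 without WT replicate 1, 2 or 3. It was 227, 300 and 243 without CALR KO replicate 1, 2 or 3. Without WT replicate 1 and WT BTZ replicate 3 it was 5198. Pdcd1 (1.41) lost its call without CALR KO replicate 1. Tigit (1.60 to 1.78) lost its call without WT replicate 2 or CALR KO replicate 1 or 2. Ctla4 (1.48 to 1.64) and Klrd1 (1.72 to 2.32) lost their calls without WT replicate 2 or 3 or CALR KO replicate 1, 2 or 3. Lag3 (1.33 to 1.53) lost its call without WT replicate 2 or CALR KO replicate 1, 2 or 3. Mrc1 (1.28 to 1.58) lost its call without WT replicate 3 or CALR KO replicate 1 or 3. Oas1a (-1.29 to -1.52) lost its call without CALR KO replicate 1, 2 or 3. Isg15 (-1.22 to -1.53) lost its call without WT replicate 3 or CALR KO replicate 1, 2 or 3. The number of interferon-stimulated genes that rose was 0 by edgeR (1 at an unadjusted p under 0.05) without WT replicate 2 or CALR KO replicate 1 or 3. In the refits without 1 library 2 to 12 cytotoxic effector genes, 2 to 8 T cell genes and 0 to 5 checkpoint genes were higher, and camera called these 3 lists in each. Without WT replicate 1, 6 natural killer cell, 8 macrophage, 3 skeletal muscle and 5 interferon-stimulated genes were higher, and without any other of the 6 libraries 1 natural killer cell gene was. Without WT replicate 2, 5 interferon-stimulated genes were lower. Fitted on the 6 compared libraries alone, a choice made after seeing the data, 458 genes passed, and Tigit, Ctla4, Lag3, Klrd1, Oas1a and Isg15 were not called.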

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

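Differences between BTZ effects come first, each past its threshold in the test of the difference itself, and then 3 patterns, of which the keratinocyte and T cell genes are BTZ effects within 1 genotype. Tests chosen after the result was seen were both keratinocyte tests, the macrophage and B cell tests of the T cell genes and the population test of the S phase genes. In AMO1, 2829 genes differed in their BTZ effect between libraries labelled STING KO and WT. Beside each list that camera called stand its mean log2 difference and, second, its adjusted p with an estimated correlation. Higher in the former, with mean and adjusted p, were heat shock chaperones (0.234, 0.184), ER chaperones and unfolded protein response (0.543, 0.018), DNA replication (0.895, 0.0124), mitosis (0.506, 0.0718) and danger signals and phagocytosis signals (0.231, 0.184). Lower lists, given alike, were the integrated stress response (-0.473, 0.0819), NRF2 and oxidative stress (-0.259, 0.184), BCL2 family and death receptors (-0.158, 0.184), p53 targets (-0.295, 0.0772) and replication-dependent histones (-0.733, 0.115). Camera's adjusted p for BCL2 family and death receptors (0.0786 without WT BTZ replicate 1, the highest of 7 such values) and for NRF2 and oxidative stress (0.0576 without STING KO BTZ replicate 3) lay above 0.05. Genes with a higher effect, as log2 differences, were MB21D1 (0.61), NAT8L (1.55), CDC6 (1.55), NANOS1 (1.41), SH2D5 (1.39), SAPCD2 (1.38), IFIT3 (0.90) and RSAD2 (1.34). Further ones were DNAJB1 (0.79), PDIA4 (0.95), HSPA5 (0.87), RRM2 (0.99), MCM4 (0.97), AURKB (1.29), UBE2C (1.24) and CALR (0.65). Genes with a lower effect were TMEM173 (-0.38), SLC7A11 (-1.99), ZNF608 (-1.80), HIST1H2BD (-1.78), HIST1H2AC (-1.75), KCNN3 (-1.75) and OAS2 (-0.62). Others were CTH (-1.60), OSGIN1 (-1.38), BCL2L1 (-0.62), BTG2 (-0.56) and CDKN1A (-0.65).

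In the tumours, 142 genes differed in their BTZ effect between CALR KO and WT. Lists with a higher mean in CALR KO, with mean and adjusted p in the same order, were DNA replication (0.671, 0.195), mitosis (1.34, 0.00657), cholesterol synthesis (0.418, 0.235), MYC and ribosome biogenesis (1.13, 0.195) and T cells (0.543, 0.594). Lists with a lower mean were NF-kB targets and inflammatory cytokines (-0.607, 0.214), proteasome subunits (-0.379, 0.788), NRF2 and oxidative stress (-1.04, 0.195), MHC class II antigen presentation (-1.35, 0.219), autophagy and ubiquitin (-0.616, 0.195), interferon-gamma response (-0.413, 0.771) and regulatory T cells and checkpoints (-0.726, 0.195). More were macrophages (-0.968, 0.195), monocytes and neutrophils (-1.84, 0.252), dendritic cells (-0.913, 0.241), fibroblasts and matrix (-1.71, 0.199), skeletal muscle (-4.63, 0.195), adipocytes (-2.47, 0.219) and mast cells (-1.43, 0.241). Without 1 library camera's adjusted p lay above 0.05 for NF-kB targets and inflammatory cytokines (0.0715 without WT replicate 2), proteasome subunits (0.262 without WT replicate 2), autophagy and ubiquitin (0.0509 without WT BTZ replicate 1), interferon-gamma response (0.225 without WT replicate 2, the highest of 5 such values) and T cells (0.154 without WT replicate 3, the highest of 4 such values). It did so too for regulatory T cells and checkpoints (0.0754 without WT replicate 2), dendritic cells (0.0715 without WT replicate 2), adipocytes (0.0856 without WT replicate 2, the highest of 2 such values) and mast cells (0.175 without WT replicate 1, the highest of 5 such values). Genes with a higher log2 difference were Slc9b1 (5.43), Slfn4 (2.91), Atp8b4 (2.48), Tmem97 (2.15), Ccna2 (1.78), Bub1 (1.62), Cyp51 (2.04) and Dkc1 (1.74). Genes with a lower log2 difference were Ckm (-6.74), Atp2a1 (-6.06), Myh1 (-5.81), Srxn1 (-2.91), Osgin1 (-3.71), Fth1 (-2.03), Apoe (-3.75), Csf1r (-2.23), Itgax (-2.18), Mmp2 (-3.36) and Acta1 (-4.63). Slfn4 (2.79 to 3.10) lost its call without WT replicate 2 or 3 or WT BTZ replicate 1 or any one CALR KO library. Atp8b4 (2.30 to 2.47) lost its call without CALR KO replicate 2 or CALR KO BTZ replicate 1 or 3. Tmem97 (2.10 to 2.20) lost its call without any one CALR KO library. Cyp51 (1.85 to 2.19) lost its call without WT replicate 3 or WT BTZ replicate 1 or 2 or any one CALR KO library. Itgax (-2.11 to -2.20) lost its call without CALR KO replicate 1 or 2 or CALR KO BTZ replicate 1 or 3.

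Keratinocyte genes were higher in BTZ-treated WT tumours. WT BTZ replicate 3 held 99.89% of the summed keratinocyte CPM of the 3 treated WT libraries. Of these 3, 1 lay above every WT control, and the others, at 24.6 and 18.1 CPM, lay among the controls at 3.75 to 34.9 CPM, which argues against BTZ as the cause of a rise of this size, and a smaller effect stays open. Skin tissue in that tumour piece is a candidate explanation, found and tested on the same data.

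T cell genes were higher in BTZ-treated CALR KO tumours, with a score difference of 1.94 on the log2 CPM scale (95% interval 1.39 to 2.49). A lower share of tumour cells would raise the markers of each host cell type alike. Endothelial genes differed by 1.1 (0.706 to 1.5) and monocyte and neutrophil genes by 1.13 (0.302 to 1.96), with intervals that reach that of the T cell genes, and plasma cell identity genes by -0.333 (-0.664 to -0.00235). Macrophage genes differed by -0.0144 with an upper bound of 0.368, which argues against a lower share as the whole cause, and a part stays open. Lymph node tissue would bring B cell genes, which differed by -0.00702 with an upper bound of 0.398. With all libraries thinned to the smallest total, the list's mean log2 fold change was 1.983 against 1.97 at full depth, which argues against depth. More T cells with the treatment and a change within T cells both stay open and were not tested.

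BTZ effects on S phase genes were higher in AMO1 libraries labelled STING KO than in WT. The mean difference of 0.895 was 0.8901 with all libraries thinned to the smallest total and 0.9357 with library totals alone, which argues against depth and scaling. Without BTZ 59.6% of tested genes differed between the populations. The design has 1 population labelled STING KO, so STING and other differences between the populations cannot be told apart.

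Other splits of the same libraries were counted for each number of genes. For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 8047, 7340, 7231, 8157, 3755, 350 and 654 genes, in the order reported above. The highest of the other splits gave 0 in each, and 1 of 10 splits, the real one, gave as many. The other splits mix the compared groups, so a real effect adds to their spread and their 0 says nothing of chance. For the differences of BTZ effects, 7 of 100 drawn splits of AMO1 gave at least the real 2829 genes, up to 5069, and 6 of 100 of the tumours gave at least the real 142, up to 1261. The 6 and 5 other splits as large each kept treated and control libraries of 1 genotype apart and mixed the other, as 19 and 19 draws did, so they hold the BTZ effect of that genotype, and the count cannot say whether chance is excluded. The remaining draws mixed both genotypes, and gave at most 0 and 0 genes, under the same limit.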

How the results depend on the processing

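Alternatives chosen after seeing the data are named above. The number of genes passing the FDR stayed within 1.5 times of the reported one in each of the 9 comparisons with RLE size factors and with library totals alone, and in the 4 tumour comparisons without Rn45s. It moved further as follows, and the cause was not tested. For BTZ in WT tumours it was 2335 with the strict filter, which tests fewer genes, and 984 with the compared libraries alone. For BTZ in CALR KO tumours it was 1147 with DESeq2, 196 with no filter and 3136 with the compared libraries alone. For the tumour difference of BTZ effects it was 871 with DESeq2, 87 with limma-voom, 73 with no filter and 2216 without both WT tumours. For CALR KO against WT tumours it was 1241 with DESeq2 and 5198 without both WT tumours. Without 1 library the count ran from 8 (without CALR KO BTZ replicate 3) to 1217 (without WT replicate 1) for the tumour difference, 227 to 3591 for CALR KO against WT and 54 to 289 for BTZ in CALR KO tumours. It ran from 2696 to 3769 for BTZ in WT tumours, and in AMO1 from 7202 to 8010 for BTZ in WT, 6699 to 7116 for BTZ in libraries labelled STING KO, 2099 to 3256 for their difference, 6431 to 6924 for those labelled STING KO against WT without BTZ and 7412 to 8092 with BTZ. Replicate numbers did not pair the libraries: deviations of same-numbered ones correlated from -0.335 to 0.204 in AMO1 and from -0.0911 to 0.343 in the tumours, and 0 and 7 of 12 libraries were closest to their own number. With the replicate block the tumour difference had 89 genes and the other 8 counts were within 1.5 times. MB21D1 in libraries labelled STING KO, not called, was at 0.00658 with DESeq2, 0.00706 with RLE, 0.0216 with the compared libraries and -0.0331 without STING KO BTZ replicate 3 to 0.0427 without STING KO replicate 2. B2M in AMO1 WT was at -0.0413 with library totals alone. Calr in WT tumours, not called, was at -0.0335 without WT replicate 2 to 0.293 without WT replicate 1. Named genes lost calls in 19 cases with limma-voom, 20 with no filter, 16 with the block and 24 with the compared libraries. Library totals alone lost 11, RLE 6 and leaving out both WT tumours 7. Refits without 1 library lost 326, and 1823 kept direction and threshold side. DESeq2 lost 0 and the strict filter 3, with no adjusted p for some genes. No list reversed. With an estimated correlation camera's calls ended in 99 cases and held in 29, so most of them rest on the preset correlation. Calls ended in 19 cases with fry, 9 with the strict filter, 11 without both WT tumours and 6 with the compared libraries. They ended in 3 with library totals alone, 3 with the block, 1 with no filter, 1 with RLE and 62 over the refits without 1 library. Among the calls for BTZ in WT tumours, 71.2% were higher with no filter, 68.8% with the strict filter and 86.9% with the compared libraries alone, against 58%, and for BTZ in CALR KO tumours 55.6% with the compared libraries alone against 87.7%. For the tumour difference it was 15.1% with no filter, 17.2% with the strict filter and 54.1% without both WT tumours, against 33.1%. The strict filter left no erythroid gene for CALR KO against WT tumours. The differences of BTZ effects use all 12 libraries, so they have no fit on fewer groups. In the tumours simulated changes of the smaller sizes were mostly missed with the few genes changed there, which gives no rate for the real data. How far depth sets this was not tested.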

Other observations

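Of the proteasome subunit genes, 7 of 32 rose with BTZ in WT tumours and 25 were not called (camera adjusted p = 0.00492, adjusted p = 0.595 with an estimated correlation). The number that rose was 16 without WT replicate 1 and 2 to 4 without any other of the 6 libraries, and camera's adjusted p was 0.361 without WT replicate 2. In CALR KO tumours edgeR called 0 of 20 heat shock chaperone genes with BTZ, and DESeq2 called 3 higher and limma-voom 0. At an unadjusted p under 0.05 these tools had 11, 11 and 10, and the list's mean log2 fold change was 0.711 (camera adjusted p = 0.00298, adjusted p = 0.48 with an estimated correlation). Of 16 cytosolic ribosomal protein genes there, edgeR and limma-voom called 0 and DESeq2 called 3 lower, with 9, 9 and 10 at an unadjusted p under 0.05 and a mean of -0.834 (camera adjusted p = 2.61e-05, adjusted p = 0.516 with an estimated correlation).

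The first principal component of log2 CPM held 53.7% of the variance in AMO1 and separated libraries labelled STING KO from WT, and the second held 33.1% and separated BTZ from no BTZ. CALR KO BTZ replicates 1 and 3 had the lowest chi-square of the tumour pairs, 12.1 per gene against 48.2 to 412, but not the highest Pearson r of log2 CPM (0.974 against 0.884 to 0.99), and still differed by more than sampling noise, as did the AMO1 pairs at 3.89 to 15.8. Rn45s, a ribosomal RNA precursor, took 0.232 to 5.29% of the counts of a tumour library.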
